A study of Mus musculus with 13 samples.

How the data were processed

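Gene expression was measured by RNA sequencing in 13 libraries of mouse cells: mouse embryonic fibroblasts (D0, 3 libraries), cells after 7 and 12 days of chemical treatment (D7, 3 libraries; D12, 2 libraries), chemically induced corneal endothelial cells labelled P1 and P8 (2 libraries each) and primary corneal endothelial cells (pCEC, 1 library). RNA was extracted with Trizol and libraries were made with the Illumina TruSeq kit from 1 ug of total RNA, per the labels' protocols. The deposited table, made by the authors, gives FPKM values (fragments per kilobase of transcript, scaled to the library total) for 54603 lines, and no step after its deposit changed a value. Bowtie 0.12.2 and the builds mm8 and mm10 are named in the submitters' processing notes, which do not say what each was used for. All 13 columns of per-sample values were used and 0 were not used. Nothing in the labels states that replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

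The lines of the deposited table did not line up across groups, and the gene of each value outside D0 was inferred, not read from the file. Taken line by line, Spearman's rho lay between 0.86 and 0.946 within groups but between -0.068 and 0.025 between groups (median -0.035). The column of gene IDs (54232 Ensembl IDs, of which 54079 matched the name table, 296 IDs of unannotated genes and 75 lines without an ID) follows the line order of the D0 columns. The columns of every other group follow line orders of their own. Each order behaves like the iteration order of a hash table with 131072 slots, in which 85.3% of adjacent IDs stood in increasing slot order. A gene was placed on a line of another group where the order of slots allowed it, within 6 positions of the probe sequence, and where its values gave whole reads in every library of the group. A value counted as whole when FPKM times gene length times library total, in the units of FPKM, lay within 0.001 of a whole number. The gene length was the rounded mean transcript length in GENCODE M21 (GRCm38), which gave whole reads for 24182 of the 25376 genes with reads in D0 (95.3%), and for the other 1194 genes the length that made the D0 values whole. Library totals came from up to 8 lines at the start of each group's columns. Expression levels of other groups were never used to place a gene.

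The placement was checked on D0, whose true IDs are known, with the IDs hidden but with lengths checked or set on D0. This favours the check. Of 25063 genes placed with all 3 libraries, 25062 were right, and with pairs or single libraries at least 99.95%. Of genes at 1 FPKM or more, 98.16 to 98.47% were right and 14 to 46 were wrongly at 0. In further runs, 20% of genes were treated as without D0 reads (the case of Krt5), so their GENCODE M21 lengths were unchecked. Of the placed genes among them, 99.97 to 100% were right. Of all so treated at 1 FPKM or more, 74.86 to 75.34% were placed right. The placement rules were refined after this check and implausible calls between D12 and D7 had been seen. In all, 95.97 to 98.72% of the lines with reads of a group were placed, holding 98.46 to 99.95% of a library's reads. Genes listed at 0 in a whole group were set aside where no line was left for them there, or where every other group had a mean of 1 FPKM or more (485 genes). A further 2390 genes were unresolved in at least 1 group, 593 of them at 1 FPKM or more, and both kinds were left out. A gene listed at 0 in a whole group remains the weakest kind of placement. After the rebuild, rho lay between 0.762 and 0.992 within groups and between 0.719 and 0.986 between groups (median 0.817).

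Depth was known only through the recovered library totals, which were 19184645, 24030674 and 18320091 reads in D0 and 18773819, 19305521 and 18158797 in D7. They were 16803087 and 15614252 in D12, 22587267 and 9997865 in P1, 16543151 and 22127817 in P8, and 20715716 in pCEC. Between 12591 and 13444 genes reached 1 FPKM per library, and the 10 most abundant genes held 8.7 to 20% of all FPKM. No replicate pair agreed within counting noise (tested on genes with at least 20 summed reads), with a chi-square per gene of at least 2.749, in D7, and of 165.3 in P1 and 710.1 in P8. Genes more than 2-fold apart between replicates numbered 104 to 128 in D7, 158 to 187 in D0, 210 in D12, 3116 in P1 and 5554 in P8.

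FPKM values are not counts, so differential expression was tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. The fit held 1 mean per group over all 13 libraries, with a trended prior (eBayes with trend) and 7 residual degrees of freedom. Genes were tested when at least 1 library reached 1 FPKM, which left 16864 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes on this scale understate the change of low genes. The 9 comparisons were D7, D12, P1, P8 and pCEC each against D0, D12 against D7, P1 against D12, P8 against P1, and pCEC against the mean of the P1 and P8 group means. For pCEC the spread comes from the other groups. Gene lists were tested with camera at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists of a comparison. Of 34 lists, 31 had at least 3 measured genes. They covered corneal endothelial, neural crest and fibroblast genes, pathways, and markers of other cell types such as macrophages, corneal epithelium and keratocytes.

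The groups, comparisons, tests, gene lists, most alternatives and the rule for naming genes were chosen before the data were examined. The rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called. These needed a mean of at least 10 FPKM in the higher group and every library of one group above every library of the other, and predicted or unnamed genes were left out. It also named up to 4 called members of each fixed list with the largest change, and a panel of 18 genes in every comparison, among them Slc4a11, Aqp1, Col8a1, Col8a2, Tjp1, Cdh2, Ncam1, Foxc1, Sox10, Ngfr, Pax3, Tfap2a, Thy1, Col1a1, Mki67 and Cdkn2a. The rule gave 331 genes, and the text leaves out most of them, preferring those whose call held without any single library. Some genes the rule named, including members of the panel, are not reported here. Krt12, Hoxa7, Hoxa9, Hoxb7, Xist and Kdm5d lie outside the rule and were chosen after their values were seen.

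The signature of primary cells was defined between pCEC and D0 replicate 1 at a difference of at least 4-fold and at least 10 FPKM in the higher of the pair. It was compared with 10000 random lists matched on mean expression over all libraries in 20 bins. Alternatives were TMM factors computed on the FPKM values (trims of 30% and 5%), quantile normalization, robust limma, no filter or a filter at 5 FPKM, pseudocounts of 0.1 and 5, no fold limit, a fit of only the groups compared, a replicate block, each replicate left out in turn, an estimated correlation in camera, and fry. For the signature, another D0 library as baseline and an 8-fold limit were tried, and for the correlations a filter at 5 FPKM and Pearson's r. Chosen after seeing the data were the fit without P8 replicate 2, voom on the recovered reads, the restriction to genes with checked reads in every group, and the table taken line by line.

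The fits were tested on simulated data with 50 genes changed per fold size. At 4-fold, 84% of changed genes were recovered for D7 against D0 (15033 genes), 86% for D12 against D7 (15058), 66% for P1 against D12 (15039), 70% for P8 against P1 (15024) and 52% for pCEC against D0 (15046). At 2-fold, recovery was 12, 14, 12, 8 and 2% for the same comparisons, so changes of that size mostly go uncalled. At most 0.067% of unchanged genes were called. Each gene was given the same spread in every library, whereas the real P1 and P8 replicates lay much further apart than those of D0 and D7. These rates therefore need not hold for the comparisons with P1, P8 or pCEC. Placement, signature, checks and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.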

Results

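Total RNA was sequenced from C57BL/6 mouse cells taken along a chemical conversion of embryonic fibroblasts toward corneal endothelial cells. The corneal endothelium is the cell layer on the inner face of the cornea that pumps ions and water out of the stroma. The 13 libraries fell into 6 groups. Mouse embryonic fibroblasts, the starting cells, gave 3 libraries (D0). Cells after 7 days (D7, 3 libraries) and 12 days (D12, 2 libraries) are labelled as chemically induced neural crest cells, the embryonic cell type from which corneal endothelium arises. Chemically induced corneal endothelial cells (ciCEC) carried the labels P1 (2 libraries) and P8 (2 libraries), which the labels do not expand. Primary corneal endothelial cells of mice at postnatal day 30 (pCEC) gave 1 library. Library totals recovered from the values lay between 9997865 reads (P1 replicate 2) and 24030674 reads (D0 replicate 2). Group levels are given as mean FPKM ± SD, with n = 3 for D0 and D7 and n = 2 for D12, P1 and P8. The log2 fold changes carry the standard error of limma and were computed on log2(FPKM + 1). Adjusted p-values are those of limma with Benjamini-Hochberg adjustment over 16864 genes, unless camera, the test for gene lists, is named. Gene positions refer to GRCm38 with the GENCODE M21 annotation.

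Replicates of the early groups lay close together. Across the 16864 genes, which are not independent replicates, Spearman's rho between libraries of a group was at least 0.989 in D0, 0.991 in D7 and 0.987 in D12. The P1 pair reached 0.915 and the P8 pair 0.762. P8 replicate 1 correlated with the P1 libraries at 0.936 and 0.906. P8 replicate 2 correlated with the D0 libraries at 0.928 to 0.93 and carried fibroblast and macrophage transcripts at high levels. Lyz2, a lysozyme of macrophages, was listed at 0 in P8 replicate 1 and at 691 FPKM in replicate 2. Krt5, a keratin of basal epithelial cells, stood at 2382 FPKM in P8 replicate 1 and was listed at 0 in replicate 2. All groups shared 1 estimate of the spread per gene. This disagreement widened the standard errors of those genes in every comparison. The closer D0, D7 and D12 replicates narrowed them, so p-values involving P1, P8 or pCEC may be too low.

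**Figure D1:**
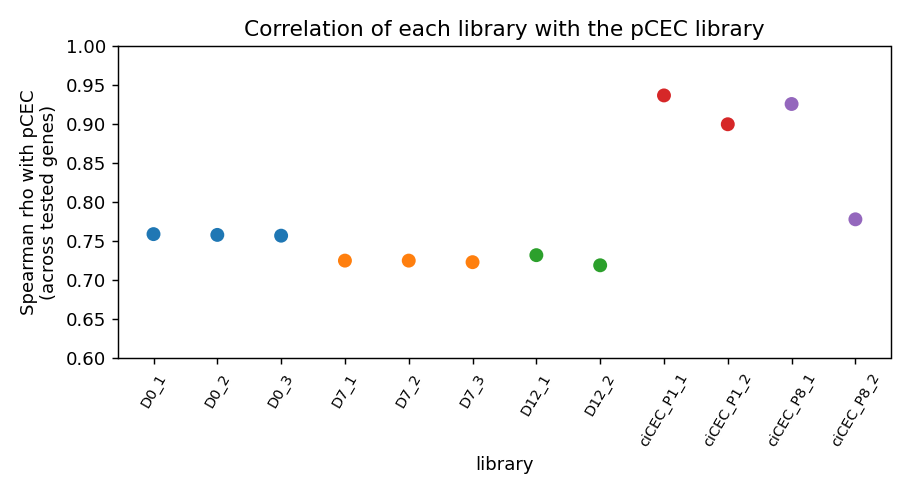
Spearman's rho across genes between each library and the pCEC library (y axis, no unit, starting at 0.6), with 1 point per library arranged by group on the x axis. The D0, D7 and D12 libraries lie between 0.719 and 0.759, the P1 libraries at 0.937 and 0.9, P8 replicate 1 at 0.926 and P8 replicate 2 at 0.778.

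The first comparison asked what changed in the first 7 days. Wnt target genes and a retinol transporter rose and solute transport genes went both ways, while macrophage, cell cycle, cholesterol synthesis and interferon-induced genes fell. Stra6, the membrane receptor that takes up retinol, rose from 0.579 ± 0.16 FPKM in D0 to 566 ± 14.8 in D7 (log2 fold change 8.49 ± 0.89, adjusted p = 0.000119). Stra6 (ENSMUSG00000032327) lies on chromosome 9 from 58063788 to 58153996 on the plus strand. Notum, an enzyme that inactivates Wnt proteins and is itself a Wnt target, rose from 0.103 ± 0.103 to 179 ± 10.3 FPKM (log2 fold change 7.35 ± 0.32, adjusted p = 1.01e-06). Notum (ENSMUSG00000042988) lies on chromosome 11 from 120653788 to 120661175 on the minus strand. Lyz2 fell from 931 ± 28.4 to 0.325 ± 0.282 FPKM (log2 fold change -9.48 ± 1.83, adjusted p = 0.00337). Lyz2 (ENSMUSG00000069516) lies on chromosome 10 from 117277331 to 117282321 on the minus strand. Ptn, a secreted growth factor, fell from 1159 ± 61.3 to 13.3 ± 1.68 FPKM (log2 fold change -6.35 ± 0.43, adjusted p = 9.79e-06). Ptn (ENSMUSG00000029838) lies on chromosome 6 from 36714929 to 36810220 on the minus strand.

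Of the Wnt targets, limma called 8 higher and 1 lower of 12 measured, and 8 higher and 1 lower adjusted over the list alone. Camera gave adjusted p = 2.46e-05, and adjusted p = 0.0594 with an estimated correlation. Nkd1, a Wnt feedback inhibitor, rose from 4.4 ± 0.576 to 135 ± 2.93 FPKM, and Apcdd1, another Wnt inhibitor, from 10.5 ± 0.668 to 435 ± 18. The neural crest list went both ways, with 7 higher and 3 lower of 18 measured, and 8 higher and 3 lower adjusted over the list alone. By camera the result was adjusted p = 0.235, and adjusted p = 0.466 with an estimated correlation. The list did pass fry, which tests whether its genes move, on balance, one way, as higher in D7 (adjusted p = 3.61e-06). Twist1, a transcription factor of mesenchyme and neural crest, rose from 43.6 ± 9.78 to 903 ± 28.4 FPKM (log2 fold change 4.36 ± 0.45, adjusted p = 0.000109). Twist1 (ENSMUSG00000035799) lies on chromosome 12 from 33957671 to 33959829 on the plus strand. Msx1 rose from 2.54 ± 0.331 to 43.4 ± 0.786 FPKM and Tfap2a from 0.879 ± 0.0229 to 18.9 ± 0.986. Sox10, a transcription factor of migrating neural crest cells, was at 1.91 ± 0.291 FPKM in D0 and 0.307 ± 0.15 in D7.

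Of the corneal endothelial transport genes, limma called 5 higher and 3 lower of 14 measured, and 5 higher and 3 lower adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.646, and 0.788 with an estimated correlation). Aqp1, a water channel, rose from 2.43 ± 0.147 to 272 ± 6.44 FPKM (log2 fold change 6.32 ± 0.76, adjusted p = 0.000275). Aqp1 (ENSMUSG00000004655) lies on chromosome 6 from 55336432 to 55348555 on the plus strand. Slc4a11, a membrane transporter whose mutation causes corneal endothelial dystrophy in humans, rose from 1.09 ± 0.108 to 9.32 ± 0.92 FPKM (log2 fold change 2.30 ± 0.41, adjusted p = 0.00234). Slc4a11 (ENSMUSG00000074796) lies on chromosome 2 from 130684113 to 130697519 on the minus strand. Col8a2, a collagen of Descemet's membrane under the corneal endothelium, fell from 11.5 ± 0.251 to 1.07 ± 0.105 FPKM (log2 fold change -2.59 ± 0.16, adjusted p = 6.30e-06). Col8a2 (ENSMUSG00000056174) lies on chromosome 4 from 126286793 to 126314330 on the plus strand.

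Macrophage, cell cycle, cholesterol synthesis and interferon-induced genes fell, with 10 of 10, 20 of 29, 14 of 18 and 13 of 18 measured members called lower, and 10, 22, 15 and 13 adjusted over the list alone. Tested as sets with camera, this gave adjusted p = 1.71e-05, 1.71e-05, 2.13e-07 and 3.47e-06, and adjusted p = 0.36, 0.641, 0.466 and 0.466 with an estimated correlation. The D0 libraries carried macrophage transcripts, with 50.5 ± 3.4 FPKM for C1qb, a complement subunit, against 0.0322 ± 0.0279 in D7. The proliferation marker Mki67 fell from 23.2 ± 1.43 to 0.987 ± 0.117 FPKM (log2 fold change -3.60 ± 0.73, adjusted p = 0.00439). Insig1, a sterol-regulated gene, fell from 98.1 ± 3.18 to 2.46 ± 0.0886 FPKM, and Isg15, an interferon-induced ubiquitin-like protein, from 91 ± 9.36 to 2.4 ± 0.517. Nuclear oxidative phosphorylation genes and genes of the mitochondrial genome rose, with 7 of 19 and 7 of 13 measured members called higher, and 8 and 7 adjusted over the list alone. In camera, adjusted p = 2.46e-05 and 0.000168, and adjusted p = 0.36 and 0.36 with an estimated correlation. The share of FPKM on mitochondrial genes was 2.55 to 2.7% in D0 and 5.9 to 6.11% in D7. Keratocyte, cytokine and glycolysis genes also rose as sets, with 3 of 7, 4 of 13 and 1 of 18 measured members called higher, and 3, 4 and 1 adjusted over the list alone. Set testing with camera returned adjusted p = 0.00445, 0.0458 and 0.0237, and adjusted p = 0.191, 0.562 and 0.641 with an estimated correlation. Neuronal genes passed too, with 4 higher and 1 lower of 6 measured, and 4 higher and 1 lower adjusted over the list alone, and contractile genes were lower, with 1 higher and 7 lower of 16 measured, and 1 higher and 7 lower adjusted over the list alone. With camera, adjusted p = 0.0376 and 0.0297, and adjusted p = 0.466 and 0.641 with an estimated correlation. The neuronal list was not called without P8 replicate 2 (camera adjusted p = 0.0944), while fibroblast, Hox and basement membrane genes then passed as lower (0.00169, 0.0489 and 0.00601). None of the 90 list calls in the 9 comparisons held when camera estimated the correlation between genes. Of the 90, 68 passed fry.

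In total 3711 genes differed between D7 and D0, 1882 higher and 1829 lower. Col1a1, the main collagen of fibroblasts, had 11470.0 ± 356 FPKM in D0 and 944 ± 18.9 in D7 and was not called (adjusted p = 0.0756). Cdkn2a, a cell cycle inhibitor, had 47 ± 2.99 and 348 ± 4.53 FPKM and was not called either (adjusted p = 0.102). Without P8 replicate 2 in the shared estimate of spread, both were called. The adjusted p was then 4.12e-05 for Col1a1, with 7.77e-07 to 0.157 over all alternatives, and 4.09e-05 for Cdkn2a, with 6.53e-07 to 0.201. The count was 2037 with a pseudocount of 5 and 6881 with no fold limit.

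Day 12 was also set against D0, the controls of day 7, so no overlap was computed. Stra6 stood at 647 ± 46.4 FPKM (log2 fold change 8.68 ± 0.99, adjusted p = 0.000243). Mt3, a metallothionein of the brain, rose from 0.238 ± 0.169 to 512 ± 164 FPKM (log2 fold change 8.66 ± 0.41, adjusted p = 2.20e-06). Mt3 (ENSMUSG00000031760) lies on chromosome 8 from 94152607 to 94154146 on the plus strand. Nefm, a neurofilament subunit, rose from 0.0878 ± 0.0455 to 106 ± 6.62 FPKM (log2 fold change 6.62 ± 0.18, adjusted p = 1.25e-07). Postn, a matrix protein of fibroblasts, fell from 1656 ± 16.1 to 16.6 ± 2.21 FPKM (log2 fold change -6.57 ± 0.67, adjusted p = 0.000129). Aqp1 reached 214 ± 9.89 FPKM (log2 fold change 5.97 ± 0.85, adjusted p = 0.000839) and Slc4a11 9.41 ± 0.338 FPKM (log2 fold change 2.32 ± 0.46, adjusted p = 0.00451). Col8a2 fell to 0.473 ± 0.0874 FPKM (log2 fold change -3.09 ± 0.18, adjusted p = 5.73e-06). The transport list was not called, with 5 higher and 2 lower of 14 measured, and 5 higher and 2 lower adjusted over the list alone, nor was the neural crest list, with 5 higher and 3 lower of 18 measured, and 6 higher and 3 lower adjusted over the list alone. For this, camera returned adjusted p = 0.601 and 0.456, and adjusted p = 0.731 and 0.657 with an estimated correlation. The neural crest list passed fry as higher in D12 (adjusted p = 0.000124), and the transport list did not (fry adjusted p = 0.332). Cell cycle, macrophage, cholesterol synthesis and contractile genes fell, with 23 of 29, 10 of 10, 14 of 18 and 7 of 16 measured members called lower, and 24, 10, 14 and 7 adjusted over the list alone. From camera came adjusted p = 9.52e-07, 3.59e-05, 8.28e-07 and 0.020, and adjusted p = 0.619, 0.458, 0.619 and 0.657 with an estimated correlation. Interferon-induced genes were lower, with 13 lower of 18 measured, and 1 higher and 13 lower adjusted over the list alone. Camera gave adjusted p = 2.80e-05, and adjusted p = 0.619 with an estimated correlation. Of the Wnt targets, limma called 7 higher and 1 lower of 12 measured, and 7 higher and 1 lower adjusted over the list alone. By camera the result was adjusted p = 0.000141, and adjusted p = 0.0954 with an estimated correlation. Nuclear oxidative phosphorylation and mitochondrial genome genes rose, with 7 of 19 and 4 of 13 measured members called higher, and 9 and 5 adjusted over the list alone. The camera test gave adjusted p = 2.15e-05 and 0.00114, with adjusted p = 0.458 and 0.458 with an estimated correlation. Fibroblast and basement membrane genes passed as lower, and cytokine, glycolysis and keratocyte genes as higher, when P8 replicate 2 was left out (camera adjusted p = 0.000222, 0.00641, 0.0204, 0.0225 and 0.032). In total 3863 genes differed, 1898 higher and 1965 lower. The count was 2285 without D12 replicate 2, 2151 with a pseudocount of 5 and 6505 with no limit on the fold change.

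Few genes separated day 12 from day 7. H19, an imprinted long noncoding RNA of embryonic tissue, fell from 576 ± 48.5 FPKM in D7 to 137 ± 8.32 in D12 (log2 fold change -2.06 ± 0.21, adjusted p = 0.00787). H19 (ENSMUSG00000000031) lies on chromosome 7 from 142575529 to 142578143 on the minus strand. Stmn3, a microtubule regulator of neurons, rose from 2.76 ± 0.34 to 11.8 ± 2.0 FPKM (log2 fold change 1.77 ± 0.16, adjusted p = 0.00613). Neither call held under every left-out library. For H19 the adjusted p was 0.0544 and 0.0576 without D7 replicates 2 and 3, and 0.0818 and 0.0901 without D12 replicates 1 and 2. It ranged from 0.000551 to 0.11 over all alternatives. For Stmn3 it was 0.0531 without D12 replicate 2 and ranged from 0.000551 to 0.566. Cell cycle genes (median log2 fold change -0.59) and Wnt targets (-0.27) were lower in D12 as sets. Of their members limma called 0 of 29 and 0 of 12 over all genes, and 0 and 0 adjusted over the list alone. Tested as sets with camera, this gave adjusted p = 0.000536 and 0.000536, and adjusted p = 0.952 and 0.0927 with an estimated correlation. Skeletal muscle and bone genes were lower in D12 too, with 0 of 7 and 1 of 6 measured members called lower, and 0 and 1 adjusted over the list alone. In camera, adjusted p = 0.0391 and 0.0296, and adjusted p = 0.242 and 0.242 with an estimated correlation. The bone list was not called without P8 replicate 2 (camera adjusted p = 0.135). Neural crest and fibroblast genes passed as lower when P8 replicate 2 was left out (camera adjusted p = 0.00637 and 0.000235).

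In total 21 genes passed between D12 and D7, 9 higher and 12 lower, while 752 had an unadjusted p under 0.05. The balance of directions was not stable. It was 8 higher and 3 lower with a pseudocount of 5, and 11 higher and 11 lower with TMM factors. Over genes with checked reads in every group it was 0 higher and 3 lower. The largest fitted changes belonged to Olfr1337 and Prep, which were listed at 0 in all libraries of D7 and of D12 respectively. A row that was not found there cannot be ruled out for either. The count was 11, 7 and 8 without D7 replicates 1, 2 and 3, and 5 without D12 replicate 2. It was 79 without P8 replicate 2 and 118 when only D7 and D12 were fitted. It was 11 and 3 with pseudocounts of 5 and 0.1, 4 with a filter at 5 FPKM, 7 with voom on the recovered reads and 3 over genes with checked reads in every group.

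The P1 ciCEC were next compared with D12, the stage before them. Interferon-induced, MHC class I and epithelial genes rose, while neuronal genes and Wnt targets fell. Lcn2, a secreted iron-binding protein of epithelia and neutrophils, rose from 2.63 ± 0.194 FPKM to 3159 ± 2451 in P1 (log2 fold change 9.51 ± 1.19, adjusted p = 0.000416). Lcn2 (ENSMUSG00000026822) lies on chromosome 2 from 32384633 to 32388252 on the minus strand. Arg1, arginase 1, rose from 0.597 ± 0.119 to 1263 ± 861 FPKM (log2 fold change 9.44 ± 0.88, adjusted p = 8.79e-05). Twist1 fell from 1084 ± 73.5 to 8.19 ± 2.66 FPKM (log2 fold change -6.91 ± 0.55, adjusted p = 3.67e-05). Mt3 fell from 512 ± 164 to 1.44 ± 1.77 FPKM (log2 fold change -7.90 ± 0.45, adjusted p = 7.70e-06). Gap43, a growth-cone protein of neurons, fell from 410.3 ± 46.3 to 0.183 ± 0.26 FPKM (log2 fold change -8.45 ± 1.45, adjusted p = 0.00213).

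Interferon-induced, MHC class I, corneal epithelium, cholesterol synthesis and glycolysis genes rose, with 16 of 18, 10 of 11, 10 of 13, 11 of 18 and 9 of 18 measured members called higher, and 16, 10, 10, 12 and 9 adjusted over the list alone. Set testing with camera returned adjusted p = 1.41e-06, 6.57e-05, 0.00409, 0.00199 and 0.000203, and adjusted p = 0.478, 0.362, 0.69, 0.69 and 0.522 with an estimated correlation. Irf7, an interferon regulatory factor, rose from 1.3 ± 0.0674 to 134 ± 11.2 FPKM (log2 fold change 5.88 ± 0.28, adjusted p = 2.94e-06), and Oasl2, an antiviral gene, from 0.586 ± 0.195 to 123 ± 75.4. Nuclear oxidative phosphorylation, neuronal and fibroblast genes fell, with 6 of 19, 3 of 6 and 5 of 20 measured members called lower, and 6, 3 and 5 adjusted over the list alone. With camera, adjusted p = 0.000203, 0.00275 and 0.038, and adjusted p = 0.362, 0.362 and 0.771 with an estimated correlation. With P8 replicate 2 left out, 12 fibroblast genes were lower and 1 higher. Of the Wnt targets, limma called 1 higher and 8 lower of 12 measured, and 1 higher and 8 lower adjusted over the list alone. For this, camera returned adjusted p = 6.57e-05, and adjusted p = 0.064 with an estimated correlation. Vascular endothelium genes were lower, with 4 lower of 7 measured, and 4 lower adjusted over the list alone. From camera came adjusted p = 0.0128, and adjusted p = 0.362 with an estimated correlation. Notum fell to 0.737 ± 0.376 FPKM (log2 fold change -6.40 ± 0.39, adjusted p = 9.93e-06).

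Among corneal endothelial genes, Tjp1, the tight junction protein ZO-1, rose from 32.8 ± 7.34 FPKM in D12 to 142 ± 21.5 in P1 (log2 fold change 2.09 ± 0.18, adjusted p = 5.70e-05). The Descemet's membrane collagen Col8a1 rose from 6.31 ± 0.908 to 63.1 ± 5.25 FPKM (log2 fold change 3.14 ± 0.30, adjusted p = 9.91e-05). Atp1b1, a subunit of the sodium pump, rose from 8.7 ± 2.32 to 124 ± 6.08 FPKM (log2 fold change 3.71 ± 0.60, adjusted p = 0.00157). Aqp1 fell from 214 ± 9.89 to 8.64 ± 5.22 FPKM (log2 fold change -4.59 ± 0.94, adjusted p = 0.00496). Nrcam, a cell adhesion molecule, fell from 66.1 ± 7.13 to 0.605 ± 0.644 FPKM (log2 fold change -5.44 ± 0.81, adjusted p = 0.00101). Neither endothelial list was called by camera. The transport list counted 6 higher and 1 lower of 14 measured, and 7 higher and 2 lower adjusted over the list alone, and the junction and matrix list 7 higher and 1 lower of 16 measured, and 7 higher and 1 lower adjusted over the list alone. Camera gave adjusted p = 0.0722 and 0.179, and adjusted p = 0.43 and 0.662 with an estimated correlation. Both lists passed fry as higher in P1 (adjusted p = 0.000693 and 0.00237). In total 4623 genes differed, 54.7% of them higher in P1. That share was 44.2% after quantile normalization, which moved the median log2 fold change of all genes from 0.12 to -0.02, and 47.8% with TMM factors. The count was 2739 without D12 replicate 2 and 2889 with a pseudocount of 5.

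Over the whole conversion, from D0 to P1, most epithelial and MHC class I genes rose, while most fibroblast and macrophage genes fell. Krt5 was listed at 0 in all 3 D0 libraries and reached 2276 ± 119 FPKM in P1 (adjusted p = 0.00993). Krt5 (ENSMUSG00000061527) lies on chromosome 15 from 101707070 to 101712898 on the minus strand. Lcn2 rose from 0.030 ± 0.0519 to 3159 ± 2451 FPKM (log2 fold change 11.33 ± 1.08, adjusted p = 0.000196). Pkp1, a desmosomal protein of stratified epithelia, rose from 0.0193 ± 0.0335 to 356 ± 45 FPKM (log2 fold change 8.44 ± 1.73, adjusted p = 0.00798). Ocln, the tight junction protein occludin, rose from 0.106 ± 0.0295 to 37.3 ± 1.08 FPKM (log2 fold change 5.11 ± 1.09, adjusted p = 0.00946). Ptn fell from 1159 ± 61.3 to 1.21 ± 0.293 FPKM (log2 fold change -9.04 ± 0.48, adjusted p = 9.65e-06). Krt14, the partner keratin of Krt5, rose from 0.333 ± 0.124 to 3551 ± 25.6 FPKM (log2 fold change 11.38 ± 2.57, adjusted p = 0.0118). Krt14 (ENSMUSG00000045545) lies on chromosome 11 from 100203162 to 100207548 on the minus strand. The adjusted p of Krt14 was 0.0567 without P1 replicate 2 and ranged from 2.69e-10 to 0.146 over all alternatives. With voom on the recovered reads, Krt5 and Pkp1 were not called (adjusted p = 0.124 and 0.0984, the highest of their alternatives, the lowest being 1.01e-10 and 3.40e-09).

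Corneal epithelium genes rose, with 11 of 13 measured members called higher, and 11 adjusted over the list alone, at a median log2 fold change of 7.16. By camera the result was adjusted p = 3.63e-05, and adjusted p = 0.506 with an estimated correlation. Of the corneal endothelial transport genes, limma called 7 higher and 1 lower of 14 measured, and 9 higher and 1 lower adjusted over the list alone. The camera test gave adjusted p = 0.000735, with adjusted p = 0.444 with an estimated correlation. Car2, a carbonic anhydrase, rose from 0.253 ± 0.144 to 102 ± 117 FPKM (log2 fold change 5.61 ± 1.01, adjusted p = 0.00452). Slc4a4, a sodium bicarbonate cotransporter, rose from 1.49 ± 0.0599 to 14.5 ± 3.37 FPKM (log2 fold change 2.62 ± 0.31, adjusted p = 0.000572). Slc4a11, at 8.23 ± 7.32 FPKM in P1, was also called (log2 fold change 1.87 ± 0.46, adjusted p = 0.0169). Its call was lost without D0 replicate 2 (adjusted p = 0.051), D0 replicate 3 (0.0519) or P1 replicate 2 (0.0658), with a range of 0.000674 to 0.0677 over all alternatives. Aqp1 was at 8.64 ± 5.22 FPKM in P1. It was not called (adjusted p = 0.25), but it was without P8 replicate 2 (adjusted p = 0.00355, with a range of 0.00355 to 0.657 over all alternatives).

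The junction and matrix genes of corneal endothelium went both ways, with 5 higher and 2 lower of 16 measured, and 6 higher and 3 lower adjusted over the list alone. Tested as sets with camera, this gave adjusted p = 0.294, and adjusted p = 0.506 with an estimated correlation. Tjp1 rose from 48.1 ± 4.72 to 142 ± 21.5 FPKM (log2 fold change 1.54 ± 0.16, adjusted p = 0.000355). Col8a2 fell to 0.15 ± 0.212 FPKM (log2 fold change -3.46 ± 0.18, adjusted p = 8.86e-06). Col8a1, at 63.6 ± 4.11 FPKM in D0 and 63.1 ± 5.25 in P1, was not called (adjusted p = 0.988). Fibroblast, cell cycle and cholesterol synthesis genes fell, with 12 of 20, 9 of 29 and 7 of 18 measured members called lower, and 17, 11 and 7 adjusted over the list alone. In camera, adjusted p = 1.99e-06, 6.69e-06 and 0.000534, and adjusted p = 0.506, 0.506 and 0.506 with an estimated correlation. Postn fell from 1656 ± 16.1 to 68.1 ± 46.7 FPKM (log2 fold change -4.77 ± 0.67, adjusted p = 0.00143). With P8 replicate 2 left out, 15 cell cycle genes and 11 cholesterol synthesis genes were called, and basement membrane genes passed as lower (camera adjusted p = 0.0176). Of the macrophage genes, limma called 1 higher and 8 lower of 10 measured, and 1 higher and 9 lower adjusted over the list alone. Set testing with camera returned adjusted p = 0.000366, and adjusted p = 0.444 with an estimated correlation. Glycolysis, MHC class I and interferon-induced genes rose, with 15 of 18, 9 of 11 and 8 of 18 measured members called higher, and 15, 9 and 9 adjusted over the list alone. With camera, adjusted p = 4.61e-09, 2.88e-05 and 0.00152, and adjusted p = 0.444, 0.444 and 0.506 with an estimated correlation. Egln3, an oxygen-sensing hydroxylase induced by hypoxia, rose from 2.01 ± 0.192 to 236 ± 71.2 FPKM (log2 fold change 6.27 ± 1.14, adjusted p = 0.00475). Of the Hox genes, limma called 2 higher and 10 lower of 30 measured, and 2 higher and 10 lower adjusted over the list alone. For this, camera returned adjusted p = 0.0122, and adjusted p = 0.444 with an estimated correlation. Contractile genes were lower, with 6 lower of 16 measured, and 7 lower adjusted over the list alone, and immediate early and heat shock genes, which also respond to the handling of cells, were higher, with 4 higher of 12 measured, and 6 higher adjusted over the list alone. From camera came adjusted p = 0.0124 and 0.0418, and adjusted p = 0.506 and 0.506 with an estimated correlation. In total 3256 genes differed, 57.5% of them higher in P1, and 2022 with a pseudocount of 5. That share was 47.2% after quantile normalization, which moved the median log2 fold change of all genes from 0.04 to -0.08, and 53.9% with TMM factors.

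**Figure D2:**
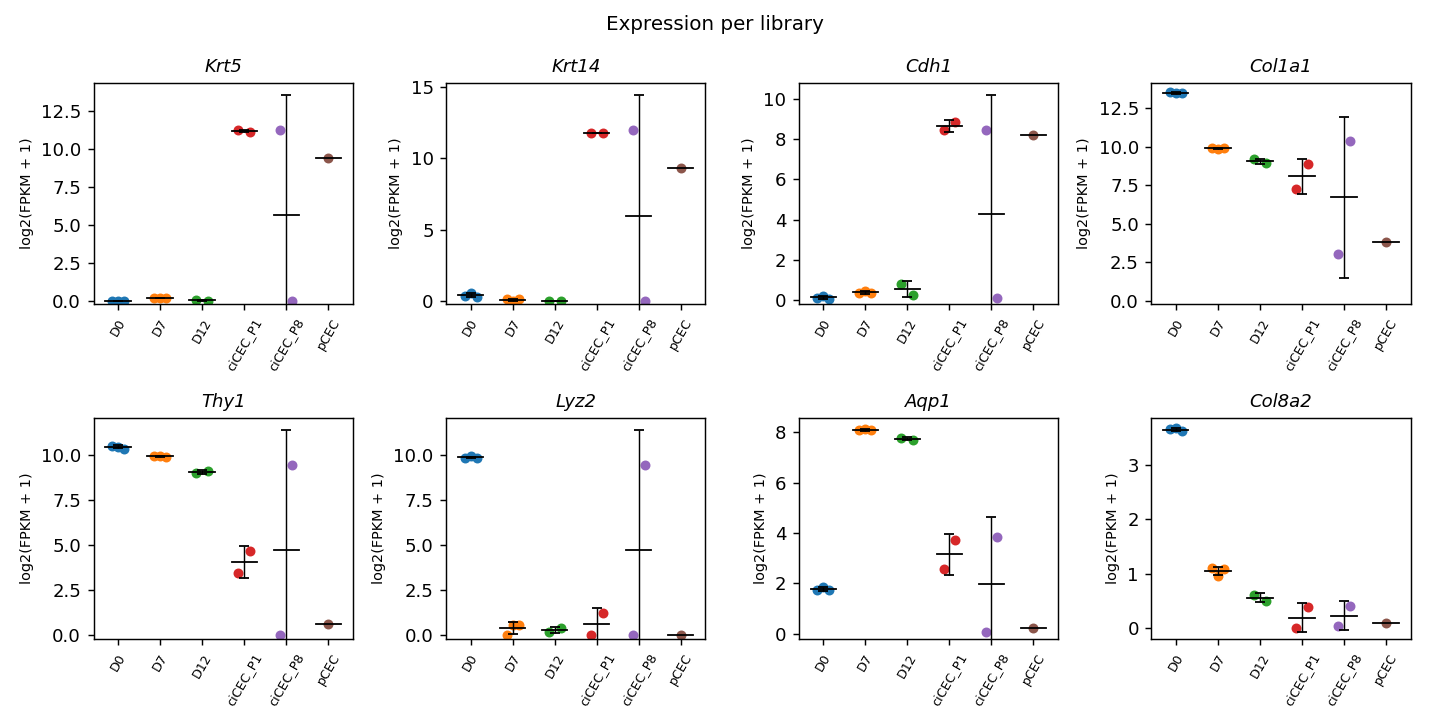
Level of 8 genes in every library, as log2(FPKM + 1) on the y axis and group on the x axis, with points for libraries, horizontal lines for the mean of the log2 values and bars for the SD (pCEC is a single point). Krt5, Krt14 and Cdh1 are high in P1, P8 replicate 1 and pCEC and near 0 elsewhere. P8 replicate 2 sits near D0 for Lyz2 and nearer to D7 and D12 for Col1a1 and Thy1, and Aqp1 is highest in D7 and D12.

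The P8 ciCEC, whose libraries stood apart, were compared with D0 likewise. Lcn2 was at 2346 and 88.8 FPKM in P8 replicates 1 and 2 against 0.030 ± 0.0519 in D0 (log2 fold change 8.80 ± 1.08, adjusted p = 0.00113). Arg1 was at 1741 and 173 FPKM against 1.04 ± 0.441 (log2 fold change 8.10 ± 0.80, adjusted p = 0.000337). H2-D1, an MHC class I gene, rose from 133 ± 7.0 to 1172 ± 72.1 FPKM (log2 fold change 3.13 ± 0.23, adjusted p = 8.55e-05). Irf7 rose from 13.2 ± 0.71 to 222 ± 104 FPKM (log2 fold change 3.89 ± 0.26, adjusted p = 5.20e-05). Tjp1 rose to 123 ± 11.1 FPKM (log2 fold change 1.34 ± 0.16, adjusted p = 0.00111). Ptn fell to 5.28 ± 5.53 FPKM (log2 fold change -7.88 ± 0.48, adjusted p = 2.75e-05) and Col8a2 to 0.177 ± 0.214 (log2 fold change -3.42 ± 0.18, adjusted p = 1.13e-05). The call of Lcn2 ended when only P8 and D0 were fitted (adjusted p = 0.0714, with a range of 9.43e-07 to 0.0714 over all alternatives).

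Glycolysis, MHC class I, interferon-induced and corneal epithelium genes were higher in P8 than in D0 as sets, with 12 of 18, 8 of 11, 6 of 18 and 1 of 13 measured members called higher, and 14, 10, 9 and 1 adjusted over the list alone. Camera gave adjusted p = 1.94e-11, 7.48e-09, 9.41e-07 and 0.00102, and adjusted p = 0.251, 0.199, 0.429 and 0.456 with an estimated correlation. Fibroblast and Hox genes were lower, with 9 of 20 and 6 of 30 measured members called lower, and 14 and 9 adjusted over the list alone. By camera the results were adjusted p = 1.06e-06 and 1.84e-05, and adjusted p = 0.429 and 0.199 with an estimated correlation. The median level of the fibroblast genes was 1.91 in P8 replicate 1 and 7.77 in P8 replicate 2 on the log2(FPKM + 1) scale, against 9.23 to 9.28 in D0. For the epithelium genes it was 8.01 and 0.05, and for the macrophage genes 0.55 and 5.1. The macrophage list was not called, with 0 of 10 measured, and 1 higher and 4 lower adjusted over the list alone. The camera test gave adjusted p = 0.0688, with adjusted p = 0.503 with an estimated correlation. Without P8 replicate 2, the calls were 11 epithelium genes, 19 fibroblast genes and 15 Hox genes (2 higher and 13 lower). The macrophage list then passed (camera adjusted p = 0.000262) and the interferon list did not (0.336). Immediate early and heat shock genes, a mark of how cells were handled as well as of their state, were higher in P8, with 6 higher of 12 measured, and 6 higher adjusted over the list alone, and 10 of 12 without P8 replicate 2. Cytokine genes were higher as well, with 6 higher of 13 measured, and 6 higher adjusted over the list alone. Tested as sets with camera, this gave adjusted p = 2.24e-05 and 9.41e-07, and adjusted p = 0.414 and 0.199 with an estimated correlation. Contractile, cell cycle inhibitor and cholesterol synthesis genes were lower, with 6 of 16, 2 of 15 and 5 of 18 measured members called lower, and 7, 3 and 10 adjusted over the list alone. In camera, adjusted p = 0.0013, 0.0283 and 1.18e-05, and adjusted p = 0.429, 0.414 and 0.429 with an estimated correlation. Basement membrane genes were mostly lower, with 1 higher and 3 lower of 13 measured, and 1 higher and 7 lower adjusted over the list alone. Set testing with camera returned adjusted p = 0.0299, and adjusted p = 0.429 with an estimated correlation. The cytokine and cholesterol synthesis lists were not called without P8 replicate 2 (camera adjusted p = 0.189 and 0.46). In total 1289 genes differed, 525 higher and 764 lower. The share of higher genes, 40.7%, was 52.4% without P8 replicate 1 and 49.5% without P8 replicate 2. The count was 4820 without P8 replicate 2 and 821 without D0 replicate 2. It was 802 with a pseudocount of 5, 2049 with no limit on the fold change and 433 when only P8 and D0 were fitted.

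P8 and P1 were then compared. Clec4a1, a lectin of myeloid cells, rose from 0.153 ± 0.0558 FPKM in P1 to 16.1 ± 7.68 in P8 (log2 fold change 3.82 ± 0.29, adjusted p = 0.000513). Cd34, a surface protein of progenitor and stromal cells, rose from 1.03 ± 0.665 to 12.9 ± 1.51 FPKM (log2 fold change 2.80 ± 0.21, adjusted p = 0.000497). Wnt7a, a Wnt ligand of epithelia, fell from 15.9 ± 8.14 to 0.0723 ± 0.102 FPKM (log2 fold change -3.89 ± 0.29, adjusted p = 0.000497). Clu, the secreted chaperone clusterin, fell from 2801 ± 1871 to 108 ± 114 FPKM (log2 fold change -5.09 ± 0.75, adjusted p = 0.0155). Slc4a4 fell from 14.5 ± 3.37 to 3.26 ± 2.12 FPKM (log2 fold change -1.94 ± 0.34, adjusted p = 0.0312). Macrophage genes were higher in P8 as a set, with 1 higher of 10 measured, and 2 higher adjusted over the list alone, and transport genes lower, with 1 lower of 14 measured, and 3 lower adjusted over the list alone. With camera, adjusted p = 0.000818 and 0.00211, and adjusted p = 0.517 and 0.517 with an estimated correlation. Cell cycle genes had a median log2 fold change of 1.08 and corneal epithelium genes of -3.33. Of these, limma called 0 of 29 and 0 of 13, and 0 and 0 adjusted over the list alone. For this, camera returned adjusted p = 1.70e-07 and 0.00492, and adjusted p = 0.603 and 0.727 with an estimated correlation. The groups overlapped for the cell cycle genes (median log2(FPKM + 1) 3.96 and 1.71 in P1, 4.6 and 2.99 in P8). Without P8 replicate 2, which carried the macrophage and fibroblast levels given above, the camera adjusted p was 0.669 for macrophage genes, 0.241 for transport genes and 0.241 for epithelium genes, whose direction then turned, while 2 cell cycle genes were called. Other lists then passed, fibroblast genes with 12 lower (camera adjusted p = 1.15e-08), cholesterol synthesis genes with 6 higher (1.15e-08), contractile genes with 4 lower (2.44e-05) and basement membrane genes with 5 lower (2.44e-05). Cell cycle inhibitors were then 1 higher and 6 lower (0.000537), and oxidative phosphorylation genes passed as a set with 0 members called (0.021).

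Further lists separated P8 from P1 as sets. Immediate early and heat shock genes were higher in P8, with 1 higher of 12 measured, and 1 higher adjusted over the list alone. From camera came adjusted p = 0.0182, and adjusted p = 0.724 with an estimated correlation. Cyclic AMP target, vascular endothelium and neuronal genes were higher, with 0 of 13, 0 of 7 and 0 of 6 measured members called higher, and 0, 2 and 1 adjusted over the list alone. Camera gave adjusted p = 0.00798, 0.024 and 0.0182, and adjusted p = 0.517, 0.517 and 0.517 with an estimated correlation. Mitochondrial genome genes were lower at a median log2 fold change of -0.75, with 0 of 13 measured, and 0 adjusted over the list alone. By camera the result was adjusted p = 0.0134, and adjusted p = 0.517 with an estimated correlation. Without P8 replicate 2 the camera adjusted p was 0.000537 for the immediate early and heat shock genes, 0.301, 0.48 and 0.303 for the next 3 lists and 0.241 for the mitochondrial genes.

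In total 195 genes differed between P8 and P1, 46 higher and 149 lower, with 2651 at an unadjusted p under 0.05. All 195 calls drew on the spread of the other groups, since limma called 0 genes when only the 4 libraries of P1 and P8 were fitted. Each library moved the count, to 1275 without P1 replicate 1, 596 without P1 replicate 2, 3729 without P8 replicate 1 and 1284 without P8 replicate 2. The share of higher genes, 23.6%, was 34.6% with TMM factors and 41.1% after quantile normalization, which moved the median log2 fold change of all genes from -0.07 to 0.05. It was 46.3% without P8 replicate 1 and 39.8% without P8 replicate 2. The count was 108 with a filter at 5 FPKM and 98 with a pseudocount of 5.

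The primary cells were compared with D0 from a single library, so its spread was borrowed from the other groups. Fibroblast genes were lower in pCEC, and MHC class I, interferon-induced and epithelial genes higher. Postn was at 1656 ± 16.1 FPKM in D0 and 0.34 in pCEC (log2 fold change -10.27 ± 0.85, adjusted p = 9.80e-05). Col1a1 was at 11470.0 ± 356 FPKM in D0 and 13.2 in pCEC (log2 fold change -9.66 ± 2.05, adjusted p = 0.00903). Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042 on the plus strand. Aldh3a1, an aldehyde dehydrogenase abundant in the cornea, was listed at 0 in D0 and at 1642 FPKM in pCEC (adjusted p = 0.00302), against 108 ± 31.1 in P1. The transport gene Car2 was at 111 FPKM (log2 fold change 6.49 ± 1.27, adjusted p = 0.00646) and Slc4a4 at 35.1 (log2 fold change 3.86 ± 0.39, adjusted p = 0.000276). Atp1b1 was at 262 FPKM (log2 fold change 2.90 ± 0.69, adjusted p = 0.0147). The transport list counted 6 higher and 1 lower of 14 measured, and 6 higher and 1 lower adjusted over the list alone, and was not called by camera. The camera test gave adjusted p = 0.121, with adjusted p = 0.465 with an estimated correlation. The list passed fry as higher in pCEC (adjusted p = 0.00488). Tjp1 was at 131 FPKM (log2 fold change 1.43 ± 0.21, adjusted p = 0.00164) and Col8a2 at 0.060 (log2 fold change -3.56 ± 0.23, adjusted p = 2.42e-05). Aqp1, at 0.18 FPKM in pCEC, was not called (adjusted p = 0.32), but was without P8 replicate 2 (adjusted p = 0.00664, with a range of 0.00145 to 0.543 over all alternatives).

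Fibroblast, contractile, cell cycle, cholesterol synthesis and Hox genes were lower in pCEC than in D0, with 16 of 20, 7 of 16, 8 of 29, 11 of 18 and 11 of 30 measured members called lower, and 19, 7, 15, 11 and 11 adjusted over the list alone. Tested as sets with camera, this gave adjusted p = 2.06e-09, 8.60e-05, 3.77e-06, 3.77e-06 and 0.000385, and adjusted p = 0.465, 0.465, 0.486, 0.465 and 0.465 with an estimated correlation. Hoxc9 was at 17.5 ± 1.18 FPKM in D0 and 0.19 in pCEC (log2 fold change -3.95 ± 0.58, adjusted p = 0.00166). MHC class I, interferon-induced and corneal epithelium genes were higher, with 10 of 11, 10 of 18 and 8 of 13 measured members called higher, and 11, 12 and 12 adjusted over the list alone. In camera, adjusted p = 3.66e-06, 3.77e-06 and 0.000323, and adjusted p = 0.465, 0.465 and 0.465 with an estimated correlation. H2-K1, an MHC class I gene, was at 77.5 ± 5.9 FPKM in D0 and 1955 in pCEC (log2 fold change 4.64 ± 0.88, adjusted p = 0.00561). Krt5, at 676 FPKM in pCEC, passed at adjusted p = 0.0455. It missed the threshold without D0 replicate 1 (0.0903), 2 (0.0903) or 3 (0.0893), with a range of 2.66e-09 to 0.164 over all alternatives. Of the macrophage genes, limma called 2 higher and 6 lower of 10 measured, and 2 higher and 8 lower adjusted over the list alone, with Cd68, a lysosomal protein of macrophages, at 47.9 ± 4.28 FPKM in D0 and 97.9 in pCEC. Set testing with camera returned adjusted p = 0.0129, and adjusted p = 0.465 with an estimated correlation. The keratocyte genes, markers of the corneal stroma, went both ways, with 1 higher and 2 lower of 7 measured, and 1 higher and 3 lower adjusted over the list alone. With camera, adjusted p = 0.0494, and adjusted p = 0.465 with an estimated correlation. Their median log2 fold change was -1.83 and their mean 0.16, and the list was not called without P8 replicate 2 (camera adjusted p = 0.155). Glycolysis genes were higher, with 7 higher of 18 measured, and 7 higher adjusted over the list alone, and basement membrane genes mostly lower, with 2 higher and 7 lower of 13 measured, and 2 higher and 7 lower adjusted over the list alone. For this, camera returned adjusted p = 0.00177 and 0.0169, and adjusted p = 0.465 and 0.465 with an estimated correlation. In total 3799 genes differed, 2189 higher and 1610 lower, and 2416 with a pseudocount of 5. The share of higher genes, 57.6%, was 50.3% with TMM factors and 48.9% after quantile normalization. Leaving out P8 replicate 2 gave 19 lower cell cycle genes.

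The last comparison set pCEC against the mean of the P1 and P8 groups, again with a borrowed spread. Aqp5, a water channel of the corneal epithelium and of glands, was at 290.1 FPKM in pCEC, 4.63 ± 5.51 in P1 and 0.184 ± 0.193 in P8 (log2 fold change 7.06 ± 0.67, adjusted p = 0.000779). Pax6, a transcription factor of eye development, was at 18.9 FPKM in pCEC, 0.56 ± 0.578 in P1 and 0.22 ± 0.274 in P8 (log2 fold change 3.88 ± 0.31, adjusted p = 0.000239). Pax6 (ENSMUSG00000027168) lies on chromosome 2 from 105668900 to 105697364 on the plus strand. Slc4a4, at 35.1 FPKM in pCEC, was higher than in ciCEC (log2 fold change 2.21 ± 0.38, adjusted p = 0.014). Col6a1, a collagen of connective tissue, was at 0.63 FPKM in pCEC and 31.1 ± 2.16 in P1 (log2 fold change -4.59 ± 0.73, adjusted p = 0.0101). Serping1, the C1 inhibitor of complement, was at 0.73 FPKM in pCEC and 56.6 ± 27.2 in P1 (log2 fold change -4.52 ± 0.36, adjusted p = 0.00025). Slc4a11, Tjp1 and Col8a2 did not pass (adjusted p = 0.729, 0.999 and 0.788).

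Fibroblast genes and junction and matrix genes were lower in pCEC than in ciCEC as sets, with 3 of 20 and 1 of 16 measured members called lower, and 4 and 3 adjusted over the list alone. From camera came adjusted p = 7.28e-07 and 0.0224, and adjusted p = 0.631 and 0.631 with an estimated correlation. Interferon-induced genes were higher, with 2 higher of 18 measured, and 4 higher adjusted over the list alone. Camera gave adjusted p = 0.00028, and adjusted p = 0.631 with an estimated correlation. MHC class I genes had a median log2 fold change of 1.09 and cell cycle genes of -0.88. Of these, limma called 0 of 11 and 0 of 29, and 0 and 0 adjusted over the list alone. By camera the results were adjusted p = 0.00762 and 0.000281, and adjusted p = 0.631 and 0.655 with an estimated correlation. Leaving out P8 replicate 2, the calls were 10 fibroblast genes, all lower, 14 interferon-induced and 5 MHC class I genes, all higher, and 4 junction and matrix genes, 1 higher and 3 lower. The corneal epithelium list was not called (camera adjusted p = 0.246, direction higher), but turned to lower in pCEC and passed without P8 replicate 2 (0.00467), with 2 members higher and 5 lower. Cytokine, contractile, glycolysis, cholesterol synthesis and immediate early and heat shock genes were lower in pCEC too, with 0 of 13, 2 of 16, 1 of 18, 1 of 18 and 1 of 12 measured members called lower, and 2, 3, 2, 1 and 1 adjusted over the list alone. The camera test gave adjusted p = 0.00028, 0.00534, 0.00762, 0.00125 and 0.014, with adjusted p = 0.631, 0.631, 0.631, 0.655 and 0.631 with an estimated correlation. The contractile list was not called without P8 replicate 2 (camera adjusted p = 0.199). In total 536 genes differed, with 3305 at an unadjusted p under 0.05. Of the 536, 74.6% were higher in pCEC, a share of 64.2% with TMM factors, 68.3% after quantile normalization and 54.7% with a pseudocount of 0.1. It was 56.8% without P8 replicate 1 and 57.2% without P8 replicate 2. The count was 0 by limma when only P1, P8 and pCEC were fitted. It was 1254 without P1 replicate 1, 845 without P1 replicate 2, 2980 without P8 replicate 1 and 1426 without P8 replicate 2. It was 332 with a filter at 5 FPKM, 291 with a pseudocount of 5 and 806 with no limit on the fold change.

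**Figure D3:**
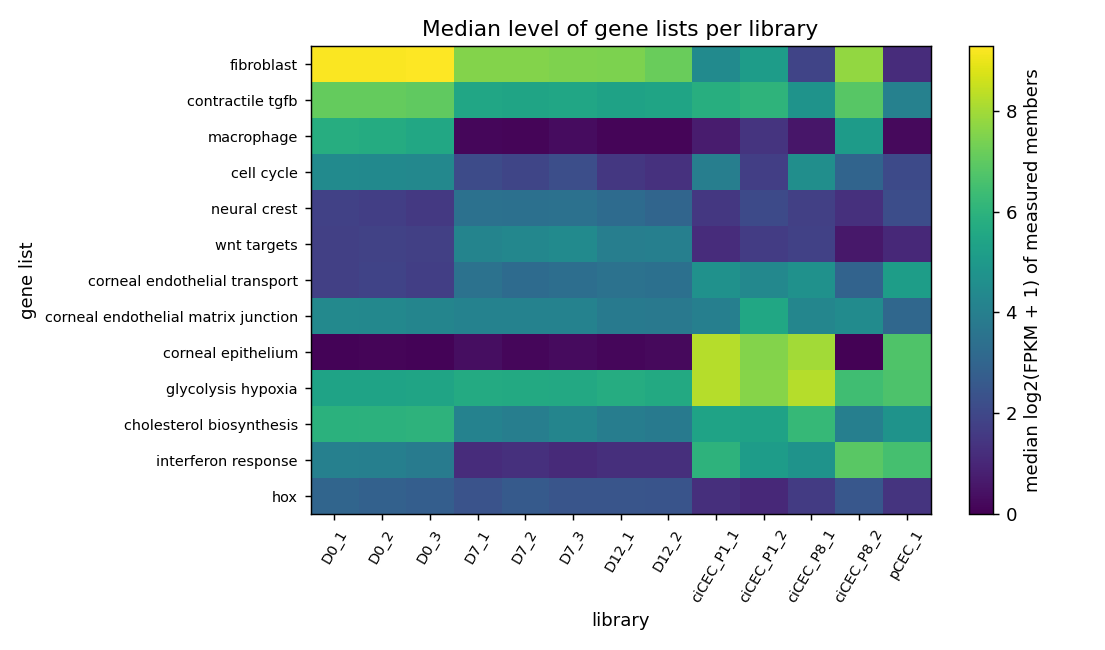
Heat map of the median level of 13 fixed gene lists (1 line of cells per list) in each of the 13 libraries (columns), as log2(FPKM + 1) of the measured members, with the colour scale giving the value. The corneal epithelium genes stand at 8.23 and 7.54 in P1, 8.01 in P8 replicate 1, 6.73 in pCEC and 0.05 in P8 replicate 2, whose fibroblast genes stand at 7.77 and macrophage genes at 5.1.

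The induced cells were also placed relative to the primary cells. Genes were taken that differed at least 4-fold between pCEC and D0 replicate 1, and changes were measured from the other D0 libraries, so that the baseline was not shared. Of these genes, 994 were higher and 729 lower in pCEC, and all values describe that single pCEC library. In that library the median log2(FPKM + 1) of corneal epithelium genes was 6.73, against 0.08 to 0.12 in D0. The median was 5.17 for transport genes (1.73 to 1.85 in D0) and 3.09 for junction and matrix genes (4.22 to 4.35 in D0). The signature did not separate epithelial from endothelial genes, so a move toward pCEC can reflect either. In P1, the median log2 change was 2.8 for the genes higher in pCEC and -2.41 for those lower, and 98.9% and 98.5% of them moved in the pCEC direction. In D7 the medians were 0.06 and -0.98, and in D12 they were 0.07 and -1.12. In P8 the medians were 1.84 and -1.92, with 2.99 and -3.34 in P8 replicate 1 and 0.18 and -0.72 in P8 replicate 2. Lists of the same size matched on expression, drawn 10000 times, had medians from -0.04 to 0.15 and -0.1 to 0.16 in P1, and from -0.17 to 0.06 and -0.15 to 0.13 in D7. Spearman's rho with pCEC across genes was 0.757 to 0.759 for D0, 0.723 to 0.725 for D7 and 0.732 and 0.719 for D12. It was 0.937 and 0.9 for P1, and 0.926 and 0.778 for P8 replicates 1 and 2.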

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

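The counts below come from comparisons planned in advance, while the tests of explanations for P8 replicate 2 and the fit without that library were chosen after the result was seen. Between D12 and D7, 21 genes had a change from D0 that differed by limma's test of the difference itself. Between P8 and P1, 195 genes did, by the same kind of test.

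P8 replicate 2 correlated with each D0 library at a Spearman's rho of at least 0.928 and with the other ciCEC libraries at no more than 0.817. It was not identical to D0, with H19 at 3.34 FPKM against 853 ± 18.6 in D0 and Arg1 at 173 against 1.04 ± 0.441. A swap with a D0 library is argued against, since the lowest rho between D0 libraries was 0.989 and the highest between a D0 library and P8 replicate 1 was 0.759. A mixture of cells like those of P8 replicate 1 with fibroblasts is argued against too, since over 10 epithelium genes the median level in P8 replicate 2 was 0.0809% of that in P8 replicate 1. A candidate explanation that stays open is a fibroblast culture under the P8 label. It could arise through a wrong label or because a ciCEC culture lost its profile, which these values cannot separate. The X-linked Xist and the Y-linked Kdm5d were chosen after their values were seen. Xist was at 62.5 FPKM in P8 replicate 2, 0.03 in P8 replicate 1 and 54.6 to 85.4 in D0, and Kdm5d at 2.86, 10 and 3.02 to 3.29. In P1 replicates 1 and 2, Xist was at 255.18 and 67.17 FPKM and Kdm5d at 0.18 and 1.8. In pCEC, Xist was at 279.06 FPKM and Kdm5d was listed at 0. The libraries of P1, P8 and pCEC thus differed in these sex-linked genes, and no comparison adjusted for the sex of the cells.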

How the results depend on the processing

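The settings without P8 replicate 2 (in comparisons that do not hold P8 and for the gene lists), voom on the recovered reads, genes with checked reads in every group (2151 of the 16864 tested genes lack them) and the table taken line by line were chosen after seeing the data, and the others were planned. Counts of changed genes stayed within 1.5 times their value with TMM factors, quantile normalization, robust limma and no filter in all 9 comparisons. Uncalled values that changed sign were not counted as reversals. Where no cause is named, the cause was not tested. In simulated data, which gave a gene the same spread in every library, 2-fold changes were recovered in at most 14% of cases.

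With a pseudocount of 5, which shrinks the fold changes of low genes, the counts were 2037 (D7 against D0), 2151 (D12 against D0), 11 (D12 against D7), 2889 (P1 against D12), 2022 (P1 against D0), 802 (P8 against D0), 98 (P8 against P1), 2416 (pCEC against D0) and 291 (pCEC against ciCEC). A pseudocount of 0.1 gave 3 for D12 against D7. A filter at 5 FPKM, which tests fewer genes, gave 4 for D12 against D7, 108 for P8 against P1 and 332 for pCEC against ciCEC. With no fold limit the counts were 6881 (D7 against D0), 6505 (D12 against D0), 2049 (P8 against D0) and 806 (pCEC against ciCEC). Fitting only the groups compared gave 118 for D12 against D7, 433 for P8 against D0, and by limma 0 for P8 against P1 and 0 for pCEC against ciCEC, where the full fit gave 2651 and 3305 genes at an unadjusted p under 0.05. By voom the last pair had 166 and 611, and D12 against D7 had 7. Genes with checked reads in every group gave 3 for D12 against D7. Taken line by line, where a line holds different genes in different groups, 43103 lines gave 20307, 20094, 19986, 21135, 21317, 20309, 20353, 20675 and 24213 calls in the same order.

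Leaving out 1 library of the groups compared gave 3094 to 3448 calls for D7 against D0, 2285 to 3511 for D12 against D0, 5 to 16 for D12 against D7, 2739 to 5176 for P1 against D12 and 2221 to 3605 for P1 against D0. It gave 821 to 4820 for P8 against D0, 596 to 3729 for P8 against P1, 2764 to 2797 for pCEC against D0 and 845 to 2980 for pCEC against ciCEC. A lone library left in a group was assumed to vary like the other groups. Without P8 replicate 2 in the shared spread, the counts were 4211, 4482, 79, 5498 and 4166 for the first 5 comparisons and 5133 for pCEC against D0.

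With the replicate number as a block, the counts were 3542 (D7 against D0), 3313 (D12 against D0), 5 (D12 against D7), 4237 (P1 against D12), 2517 (P1 against D0), 889 (P8 against D0) and 51 (P8 against P1), and 66 of 68 list calls held. The labels do not say that the numbers pair the samples. Deviations of libraries sharing a number correlated at 0.006, 0.012 and -0.049 between D0 and D7, the groups with 3 such pairs, and at -0.234 to 0.182 between the other groups. No paired analysis was possible for pCEC because it has 1 library.

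The lists called by camera numbered 12, 8, 4, 10, 13, 12, 9, 12 and 10 in the same order, and 0 in every comparison with an estimated correlation. By fry they were 19, 18, 18, 25, 20, 2, 21 and 2 for D7 and D12 against D0, P1 against D12 and D0, P8 against D0 and P1, and pCEC against D0 and ciCEC. Without P8 replicate 2, 13 were called for D12 against D0, 76 of the 90 calls held, 13 were lost, and the corneal epithelium list turned direction between P8 and P1 (camera adjusted p = 0.2409). Among named genes, mt-Co1 in pCEC against D0 had a log2 fold change of 1.29 that became -0.21 (adjusted p = 0.757) after quantile normalization. Of the calls and values of named genes, 842 held with TMM factors against 17 lost and 2 gained, 691 held in a fit of only the groups compared against 151 lost and 19 gained, 723 held with a pseudocount of 5 against 135 lost and 3 gained, and 723 held with voom against 133 lost and 5 gained.

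The signature medians in D7 for genes higher in pCEC were 0.08 and 0.08 with D0 replicates 2 and 3 as definition, 0.18 with a pseudocount of 0.1 and 0.03 with 5. For genes lower in pCEC they were -1.03 and -1 with those D0 libraries, -1 with a pseudocount of 0.1 and -1.1 at 8-fold. In D12 they were 0.1, 0.11, 0.22 and 0.03 for the higher genes and -1.29 at 8-fold for the lower genes. In P1 they were 3.16 and 2.4 with pseudocounts of 0.1 and 5 and 3.73 at 8-fold for the higher genes, and -2.56, -2.12 and -3.03 for the lower genes. Over genes at 5 FPKM or more, Spearman's rho with pCEC was 0.655, 0.655 and 0.653 in D0, 0.611, 0.611 and 0.609 in D7, 0.622 and 0.602 in D12, 0.915 and 0.87 in P1 and 0.895 and 0.69 in P8. Pearson's r was 0.763, 0.763 and 0.76 in D0, 0.738, 0.738 and 0.736 in D7 and 0.744 and 0.733 in D12.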

Other observations

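The gene groups of the first 2 paragraphs were picked after their values were seen, apart from the cytokine list, and all tests of explanations in this part were chosen after the result was seen. The imprinted genes H19, Cdkn1c and Peg3 were lower in P1 than in D0, and other imprinted genes were not tested as a set. H19 fell from 853 ± 18.6 FPKM in D0 to 3.0 ± 1.67 in P1 (log2 fold change -7.81 ± 0.21, adjusted p = 2.17e-07) and 3.42 ± 0.111 in P8 (log2 fold change -7.59 ± 0.21, adjusted p = 2.78e-07), and was at 0.040 in the single pCEC library (log2 fold change -9.68 ± 0.27, adjusted p = 1.76e-07). Cdkn1c, a cell cycle inhibitor expressed from the maternal copy, fell from 61.4 ± 4.15 FPKM in D0 to 1.08 ± 0.144 in P1 (log2 fold change -4.90 ± 0.31, adjusted p = 2.38e-05). Peg3, expressed from the paternal copy, fell from 299 ± 41.1 to 2.16 ± 1.37 FPKM (log2 fold change -6.63 ± 0.87, adjusted p = 0.000991). H19 fell to a similar level in both P8 libraries, 3.5 and 3.34 FPKM.

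The chemokines Cxcl1 and Cxcl5 were higher in P1 than in D0. Cxcl1, a neutrophil attractant, rose from 1.19 ± 0.241 FPKM in D0 to 47.8 ± 1.6 in D7 (log2 fold change 4.48 ± 0.35, adjusted p = 2.08e-05) and 91.2 ± 66.8 in P1 (log2 fold change 5.18 ± 0.39, adjusted p = 6.71e-05). Cxcl5 rose from 12.9 ± 0.795 to 716 ± 83.2 FPKM (log2 fold change 5.68 ± 0.77, adjusted p = 0.00116). Of the cytokine and inflammation genes, limma called 7 higher of 13 measured, and 7 higher adjusted over the list alone, between P1 and D0. The list's camera result was adjusted p = 0.00152, and adjusted p = 0.444 with an estimated correlation. Between P1 and D12 the list was not called by camera (adjusted p = 0.162) but passed fry as higher (adjusted p = 0.0426). Between P8 and D0 its camera adjusted p was 9.41e-07, then 0.199 with an estimated correlation, and 0.189 without P8 replicate 2, with 7 members higher and 2 lower.

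Epithelial keratins were abundant in cells labelled as corneal endothelium, at 2276 ± 119 FPKM for Krt5 in P1 and 676 in pCEC. Misplaced lines are argued against, since 10 of the 14 genes of the corneal epithelium list with values in every group were at 10 FPKM or more in P1, P8 replicate 1 and pCEC, which were placed separately. RNA of pCEC in the P1 libraries is argued against, since 8 of 10 epithelium genes were higher in both P1 libraries than in pCEC; an earlier form of this test used only Krt5 and Krt14. Mature corneal epithelium among the cells cannot be told apart from other sources, since single genes point both ways. Its keratin Krt12 reached at most 0.0039% of the Krt5 level, while Aldh3a1, Aqp5 and Pax6, all 3 of them abundant in that epithelium, were at 1642, 290.1 and 18.9 FPKM in pCEC. In P1 and P8 replicate 1, where Krt5 was highest, Aldh3a1 was at 86.4 to 130.38 FPKM, but Aqp5 reached at most 8.53 and Pax6 at most 0.97, so the genes that point toward it are mostly those of pCEC. Aqp5 was also at 218.75 and 244.35 FPKM in D12, which lacked the keratins. What stays open is the level each gene would need, since mature corneal epithelium was not analysed here. Another stratified epithelium among the cells, or expression by the labelled cells themselves, also remains possible and was not tested. Krt13 and Krt4, further epithelial keratins chosen after their values were seen, were present in the same libraries. Krt13 was at 1123.39 and 3807.26 FPKM in P1, 3159.8 in P8 replicate 1 and 1846.07 in pCEC. Krt4 was at 131.47 and 1155.29 FPKM in P1, 16.52 in P8 replicate 1 and 155.21 in pCEC. These levels do not tell the possibilities apart, since no other epithelium was analysed here.

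Hox genes, which are usually silent in the head, were present in the pCEC library, with 15.3 FPKM for Hoxa7, 16.3 for Hoxa9, 25.2 for Hoxb6 and 17.2 for Hoxb7. RNA of a whole ciCEC library in pCEC is argued against for all 4 of those sequenced here. RNA from only some of the cells of such a culture is not covered by the test, which uses the levels of the whole library. For P1 replicate 1 the 6 Hox genes at 10 FPKM or more in pCEC would need a median share of 36.4%. Of its 1152 genes at 100 FPKM or more, 7 were in pCEC at less than 10% of the level that share would bring, not counting genes listed at 0. Among them, Postn would need 36.87 FPKM and was at 0.34. The share was 74.3% for P1 replicate 2, with 38 such genes. For P8 replicates 1 and 2 it was 144% and 155%, which exceeds the whole library, with 15 and 103 such genes at a share of 100%. Expression in the primary cells, or RNA of other cells, stays open and was not tested. This test was revised after earlier forms had been seen, which used ratios of Hox genes, single fibroblast or Y-linked genes, and the percentage of genes lying under a smaller margin.

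For D7 against D0, a fit on the 6 libraries alone called 4321 genes, and the highest of the other splits called 1. With 10 splits, of which 1 reached the real count, the share cannot fall under 0.1, too few for a test at 0.05.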
